A study of Macaca mulatta with 21 samples.

How the data were processed

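Messenger RNA of rhesus macaque cell lines was measured on Affymetrix rhesus expression arrays, with 3 arrays (A, B and C) for each of 7 lines, 21 arrays in all. Total RNA was purified, per the labels, with Trizol and spin columns from manually picked undifferentiated colonies of the pluripotent lines and from trypsinized fibroblasts, then labelled with the one-cycle protocol. Mouse embryonic fibroblasts served as feeder cells for every line, the skin fibroblasts included. The labels call A, B and C biological replicates of a line; each line is a single derivation, so each test between lines speaks for those lines alone.

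The deposited values are log2 intensities per probe set that the authors made with RMA (robust multi-array average), per the labels. The version of RMA and its chip description are not given in the sources used here. All 52865 probe sets had values between 2.09 and 14.7, and the array medians lay between 4.98 and 5.14. No pair of arrays was identical, and the highest correlation between 2 arrays was 0.996. The number of arrays limits the precision of every value.

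Of the probe sets, 24969 carried 1 gene symbol, 361 carried several and 27535 carried none; those with several or none were left out of the gene tests. Each of the 14132 genes was read from its probe set with the highest mean over all arrays. Genes at log2 of 5 or more on at least 3 arrays were tested, which left 11142 genes. Values under log2 5 lie near background, so where the dimmer line averages under 5 the log2 difference is no measured ratio. A fold change printed for such a gene is a lower bound counted from log2 5, while most such genes carry the log2 difference alone. The bound is under 2-fold for some called genes. Examples are CCNE2 (1.77) and PDK1 (1.95) in CRES-3 against the fibroblasts, CA5B (1.41) and HOXA5 (1.47) in CRES-1 against RiPS1, and HOXD13 (1.91) in RiPS2 against ORMES23. The dimmer line averaged under log2 5 for 41 of 75 named genes of CRES-3 and 37 of 74 of RiPS3 against the fibroblasts. Against the induced line of their sex it did so for 2 of 8 (CRES-3) and 11 of 26 (CRES-1). Against ORMES23 it did so for 3 of 6 (CRES-1), 5 of 23 (CRES-3), 10 of 24 (RiPS1), 9 of 20 (RiPS2) and 8 of 19 (RiPS3). Chromosomes and gene order came from the rhesus assembly telomere-to-telomere MMU8v2.0, which placed 423 tested genes on the X chromosome and 10586 on autosomes; no coordinates are given.

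Differences between lines were fitted with limma 3.58.1 in R 4.3.3, in a single linear model with a mean per line and 14 residual degrees of freedom, followed by empirical Bayes moderation. P-values were two-sided and adjusted by Benjamini-Hochberg over all genes tested in a comparison. Without any difference, a share of 0.05 of the 11142 genes would be expected at an unadjusted p under 0.05. A gene was called, and is said to have risen or fallen, at an adjusted p under 0.05 with a fold change of at least 2. Errors are the standard error (SE) of the log2 difference from that model, or the standard deviation (SD) over the 3 arrays of a line. Comparisons of routes and of labelled sexes used a mean per line, so that the line was the replicate. The difference between the comparisons of cloned and induced lines in the 2 sexes was tested as an interaction, a test added after the data were seen.

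There were 24 gene lists, fixed before the data were examined, of which 23 had enough measured genes to test; they held 663 genes, 412 of them measured. Each list was tested with limma's camera at a preset correlation of 0.01, adjusted over 207 list tests, and again with an estimated correlation. Of 42 list calls, 10 also passed with the estimated correlation. The X-linked genes were tested the same way in a family of 39 tests, and the X to autosome level of the 6 pluripotent lines with an exact permutation test. Named genes followed a rule also fixed before the data were examined: the 8 largest rises and the 8 largest falls among called genes whose arrays did not overlap between the lines, up to 5 members with the smallest p from each list described, and the reprogramming factors. Non-overlap of 3 against 3 arrays happens by chance in 10% of genes. NANOG, CD9, CCNE2 and FBN1 were named after their values were seen.

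The adjusted p threshold, without the fold change limit, was tested on simulated data with 200 changed genes among 11142, in 20 draws per comparison. False calls averaged 4.38% to 5.76% over the comparisons, and reached 10.2% in a single draw for RiPS1 against ORMES23. For CRES-3 against RiPS3, 80.9% of genes shifted by log2 1 and 97.6% of those shifted by log2 2 passed in the right direction. For CRES-1 against ORMES23 these shares were 79.1% and 96.8%. They hold for 200 changed genes with noise independent between genes. With fewer changed genes the adjusted threshold is stricter, and the real arrays share an axis of spread within lines. The shares therefore do not show that few genes differ where few were called. The share called with the fold limit was not counted, and at log2 1 it would be lower, because that shift equals the limit.

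Arrays of the same letter were checked for pairing through the correlation of their deviations from the line means. All 3 letters exceeded 0.1 for CRES-1 against RiPS1 alone, with correlations of 0.318, 0.330 and 0.348. Arrays A, B and C also scored alike on the first component of the spread within lines. The scores were 5.85, 8.84 and -14.7 in CRES-1 and 10.1, 11.5 and -21.6 in RiPS1. A pairing of samples cannot be told from a shared axis of spread in this comparison, and the labels state none. The counts given come from the fit without a block; with the letter as a replicate block this comparison called 235 genes, 57 higher and 178 lower, and the block was also run for every other comparison between lines. Alternatives covered the filter on dim probe sets, quantile normalization and median centring, the mean of all probe sets of a gene, the variance model, a fit of only the arrays compared, the fold change limit, other list tests and each array or line left out. Comparisons with ORMES23 or with the fibroblasts share control arrays, so 20 simulations of unchanged groups gave the correlation and covariance that sharing produces.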

Results

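Gene expression was measured in 6 pluripotent lines of rhesus macaque and in skin fibroblasts, with 3 arrays per line. ORMES23 is a male embryonic stem cell line from a blastocyst fertilized in vitro. CRES-1 (male) and CRES-3 (female) are embryonic stem cell lines from blastocysts cloned by somatic cell nuclear transfer. RiPS1 (male, from fetal fibroblasts), RiPS2 (female, donor aged 10 years) and RiPS3 (female, donor aged 8 years) are induced pluripotent lines made with retroviral OCT4, SOX2, KLF4 and cMYC. The fibroblasts came from the skin of an adult female aged 8 years. The title of the series concerns X inactivation, and the lines allow 3 questions: what each route of reprogramming changed, how cloned and induced lines differ, and how X-linked genes compare between labelled sexes.

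The pluripotent lines resembled each other closely and the fibroblasts little. Mean absolute differences between line means ran from log2 0.17 to 0.31 within the pluripotent lines and from 0.90 to 0.98 against the fibroblasts. CRES-3 and RiPS3 formed the closest pair, with a correlation of 0.992 across genes, while correlations with the fibroblasts lay between 0.750 and 0.774. POU5F1 (OCT4), the core pluripotency factor, stood at 11.9 ± 0.46 (SD, n = 3) in ORMES23 and at 4.14 ± 0.68 in the fibroblasts. MYC was near 10 in ORMES23 (10.1 ± 0.35) and at 9.41 ± 0.31 in the fibroblasts.

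Reprogramming by nuclear transfer was examined with CRES-3 against the fibroblasts. The design text of the series says that cloned and induced lines came from the same fibroblasts, but the labels name no donor for CRES-3. This is therefore a difference between 2 lines and is not known to be one from a line's own donor. POU5F1 (probe set MmuSTS.2285.1.S1_at) rose at least 184-fold, counted from the filter level of log2 5, under which the fibroblasts lay; its log2 difference was 8.39 (SE 0.26, n = 3 per line). SOX2, its partner factor, rose by 7.76 (SE 0.19), the let-7 antagonist LIN28B by 7.72 (SE 0.13) and the de novo DNA methyltransferase DNMT3B by 7.78 (SE 0.19). The mRNA-binding protein IGF2BP3 rose by 8.36, SPP1, which encodes osteopontin, by 8.03, FAM89A by 7.95 and the transcription factor NFE2L3 by 7.60. EFEMP1, an extracellular matrix gene, fell by 9.57 (SE 0.58), with C1QTNF3 at -8.20, TNC (tenascin C) at -8.06, CTHRC1 at -8.06, TGFBI at -7.92, CHP2 at -8.00, CCDC80 at -7.83 and FGL2 at -7.07. In all, 3709 of 11142 genes were called, 2129 higher and 1580 lower in CRES-3.

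Among 20 measured pluripotency genes, 15 rose, 2 fell and 3 were not called (adjusted p = 3.68e-05, and 0.0316 with an estimated correlation). DPPA4 rose by 6.02. The members that fell were CD9, a membrane tetraspanin (-1.83), and NANOG (-1.78), whose single named probe set read 9.96 in the fibroblasts and 8.18 in CRES-3; a level this high in fibroblasts leaves it uncertain whether that probe set measures NANOG. Fibroblast genes fell in 28 of 37 cases and 1 rose (adjusted p = 5.12e-09, and adjusted p = 0.0646 with an estimated correlation); examples are the mesenchymal factor PRRX1 (-5.12), the surface protease FAP (-5.56), the protease inhibitor TIMP1 (-4.12) and the collagen gene COL6A1 (-4.03). The fibroblast gene that rose was FBN1 (1.05), whose probe sets disagreed in direction. Epithelial genes rose in 12 of 21 cases (adjusted p = 3.22e-05, and 0.0316 with an estimated correlation), among them EPCAM (6.82), the desmosome gene DSP (6.63), the claudin CLDN6 (6.45) and the keratin KRT19 (6.15). HOX genes, which set position along the body axis, fell in 13 of 19 cases (adjusted p = 2.68e-06, and 0.0484 with an estimated correlation), with HOXA9 at -5.93, HOXC6 at -4.20 and HOXB6 at -3.27. Cell cycle genes rose in 18 of 22 cases (adjusted p = 0.00116, and adjusted p = 0.685 with an estimated correlation), for example the replication licensing genes MCM3 (2.99) and MCM2 (2.53) and the cyclin CCNE1 (2.13), while CCNE2 fell by 1.54. The fibroblast arrays differed widely among themselves on this list, with a mean of 8.25 ± 1.02 (SD, n = 3), against 9.86 ± 0.07 in CRES-3. Adjusted over the list alone, the counts of these 5 lists did not differ from those over all genes. Of the reprogramming factors, KLF4 fell by 1.88 (SE 0.36) and MYC was not called, at 0.49.

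The same question for the 4-factor route was put with RiPS3, whose labels give the age and sex of the fibroblast donor but not whether these fibroblasts are its cells. IGF2BP3 rose at least 196-fold, by log2 8.37 (SE 0.26, n = 3 per line), SPP1 by 8.33, POU5F1 by 8.00 (SE 0.26), SOX2 by 7.64 (SE 0.19), FAM89A by 7.63, DNMT3B by 7.48, LIN28B by 7.29 and the RNA-binding protein RBPMS2 by 7.28. EFEMP1 fell by 8.65 (SE 0.58), with C1QTNF3 at -8.17, CTHRC1 at -7.65, TNC at -7.50, the proteoglycan LUM at -7.22, FGL2 at -7.18, CCDC80 at -7.04 and CHP2 at -7.04. A total of 3621 genes were called, 2040 higher and 1581 lower in RiPS3.

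In RiPS3, 13 of 20 pluripotency genes rose and 2 fell (adjusted p = 3.22e-05, and 0.0316 with an estimated correlation), with DPPA4 at 6.57, CD9 at -1.99 and the same uncertain NANOG probe set at -1.15; without fibroblast array A it stood at -0.86 and was not called. Fibroblast genes fell in 28 of 37 cases (adjusted p = 9.28e-09, and adjusted p = 0.0713 with an estimated correlation), including FAP (-5.33), PRRX1 (-4.90), COL6A2 (-4.11) and TIMP1 (-3.95), and FBN1 rose by 1.11, reversed with the mean of its probe sets. Epithelial genes rose in 15 of 21 cases (adjusted p = 3.76e-06, and 0.0316 with an estimated correlation), with EPCAM at 7.16, KRT19 at 7.08, DSP at 6.84 and CLDN6 at 6.43. HOX genes fell in 13 of 19 cases (adjusted p = 1.04e-05, and adjusted p = 0.0578 with an estimated correlation), with HOXA9 at -5.47 and HOXB6 at -3.03. Cell cycle genes rose in 18 of 22 cases (adjusted p = 0.000597, and adjusted p = 0.671 with an estimated correlation), with MCM3 at 3.10 and CCNE1 at 2.08, while CCNE2 fell by 1.38. The wide spread of the fibroblast arrays on this list (SD 1.02) applies here too. Adjusted over the list alone, these counts were the same. KLF4 (-0.69) and MYC (0.71) were not called.

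The changes of CRES-3 and RiPS3 against the fibroblasts were alike. Both comparisons called 3322 genes, 1867 higher and 1455 lower, and none in opposite directions, where independent lists would share 389.8 and 224.2. Their log2 differences correlated at r = 0.984 across genes, which are not independent replicates, with a covariance of 2.02. Unchanged groups against shared fibroblasts gave 0.502 and 0.0272 in simulation, so array noise shared through the controls accounts for little of the covariance. A deviation common to all 3 fibroblast arrays would enter both comparisons. It was not tested, as these arrays are too few to divide between the comparisons.

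Between the routes in female lines, CRES-3 and RiPS3 differed in 4 genes. SVOPL, a transporter-like gene, was at least 2.69-fold higher in CRES-3 (log2 1.85, SE 0.29, n = 3 per line) and the sulfotransferase gene CHST8 2.10-fold higher (1.07, SE 0.17). The calcium-binding protein gene S100A6 fell by 1.94 (SE 0.31), with the zinc finger gene ZNF662 at -1.30 (SE 0.18). Mesoderm genes were lower as a group, with a median of -0.97 over 13 members, none called alone over all genes or adjusted over the list alone (adjusted p = 5.25e-06, and adjusted p = 0.0765 with an estimated correlation). Examples are HAND1 at -1.94, the brachyury gene TBXT at -1.09 and BMP4 at -1.07. The size depends on single arrays: the median was -0.44 without RiPS3 A, -0.55 without CRES-3 A and -0.62 without RiPS3 B, and the list passed each time. KLF4 stood at -1.18 and was not called. Smaller medians passed for epithelial (-0.09), HOX (-0.15), fibroblast (-0.17) and TGF-beta and nodal genes (-0.19), and for glycolysis genes (0.18). With an estimated correlation their adjusted p lay at 0.0713, 0.131, 0.457, 0.166 and 0.484. In both lines 7 of 19 HOX members and 5 of 37 fibroblast members lay under log2 5, so for these a shift near background stays open. Without RiPS3 A the fibroblast and glycolysis lists did not pass, and the epithelial median was -0.20 without CRES-3 A and -0.03 without CRES-3 C. The TGF-beta and nodal list did not pass without CRES-3 A, CRES-3 C, RiPS3 A or RiPS3 B, and its median ran from -0.47 without RiPS3 C to 0.01 without RiPS3 A. By limma, 882 genes had an unadjusted p under 0.05. The count was 2 without CRES-3 A, 1 without CRES-3 B, RiPS3 B or RiPS3 C, and 20 without RiPS3 A; a fit of these arrays alone called 7 genes, none of the 4 above among them.

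In male lines, CRES-1 and RiPS1 differed in 238 genes, 59 higher and 179 lower in CRES-1. The apoptosis inhibitor gene FAIM was at least 5.02-fold higher in CRES-1 (log2 3.83, SE 0.32, n = 3 per line) and the paternally expressed imprinted gene PEG3 at least 3.68-fold higher (2.80, SE 0.31), both under log2 5 in RiPS1. The ubiquitin-like gene UBD rose by 3.39, DHRS2 by 3.19, the immediate early gene FOS by 2.85, ATP8A2 by 2.70, RGS4 by 2.31 and SEMA3C by 2.16. LRRC63 fell by 3.67 (SE 0.29), with the collagen gene COL6A3 at -2.85, the actin-bundling gene LCP1 at -2.69, the X-linked blood group gene XG at -2.48, HOXD1 at -2.47, LOC708877 at -2.37, EBF2 at -2.23, TTLL6 at -2.18 and the imprinted gene DLK1 at -1.62.

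X-linked genes made up 45 of the 238, and 1 of them was higher in CRES-1. Genes reported to escape X inactivation had a median of -0.65; 4 of 20 fell and none rose (adjusted p = 7.70e-09, and 0.0316 with an estimated correlation), among them CTPS2 (-1.34), EIF2S3 (-1.25) and CA5B (-1.12). Genes subject to X inactivation had a median of -0.14 (-0.09 without RiPS1 A) and fell in 9 of 93 cases (adjusted p = 0.000286, and adjusted p = 0.140 with an estimated correlation), for example CFP (-1.73), PRPS2 (-1.44), PHKA2 (-1.20) and FGD1 (-1.10). Stress genes rose in 2 of 13 cases, FOS and JUNB (1.18; adjusted p = 0.0499, and adjusted p = 0.471 with an estimated correlation). HOX genes had a median of 0.24 and a pair of calls in opposite directions, HOXA5 at 1.04 and HOXD1 (adjusted p = 0.0189, and adjusted p = 0.289 with an estimated correlation). Of the 19 HOX members, 4 lay under log2 5 in both lines. Epithelial genes had a median of 0.27 and no calls (adjusted p = 0.00986, and adjusted p = 0.115 with an estimated correlation). Adjusted over the list alone, the counts of these 5 lists were the same. RGS4 lost its call without the filter, with the mean of its probe sets and without most single arrays, and FOS without 4 of the 6 arrays; 43.1% of called genes were higher under median centring, against 24.8%. The stress list did not pass without CRES-1 B, CRES-1 C or RiPS1 B, with medians from 0.09 without CRES-1 C to 0.58 without RiPS1 A, nor the HOX list without CRES-1 A or RiPS1 C. Without RiPS1 B, 39 genes were higher.

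Across the routes at the level of lines, with 2 cloned lines against 3 induced lines, limma called 0 genes. By limma, 79 of 11142 genes had an unadjusted p under 0.05. That is fewer than the share of 0.05 expected without any difference, so the 79 are no hint of a route effect. Every alternative setting and each induced line left out also gave 0 called genes. With so few lines, and with both sexes inside each route, this test can miss a route effect, so the 0 does not show that there is none. The 5 genes with the smallest p, none of them called, were the matrix gene TGFBI at -1.13, ITPA at -1.19, ZC3H12C at 0.66, the kinase gene WNK1 at -0.78 and LOC703511 at -0.81 in cloned minus induced lines.

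**Figure D1:**
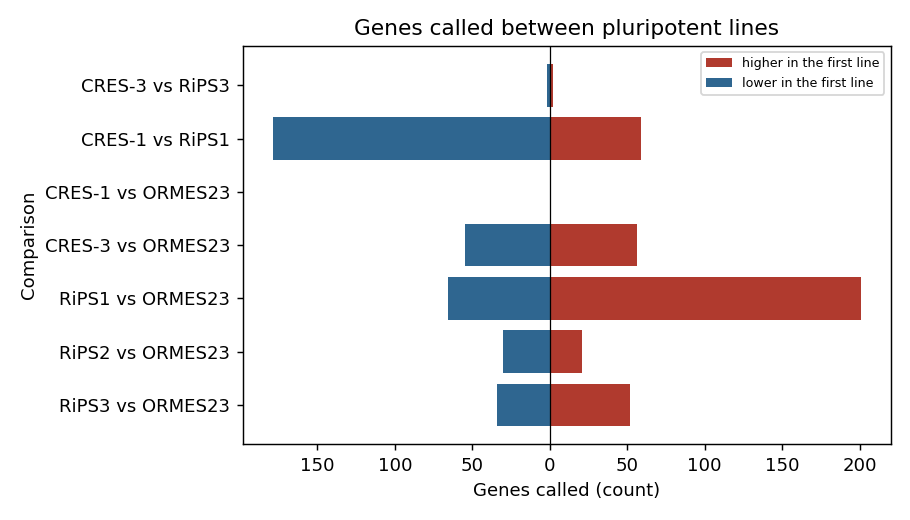
Number of genes called in 7 comparisons between pluripotent lines, cloned against induced lines of 1 sex and each line against ORMES23 (horizontal axis, a count), drawn to the right for genes higher in the line named before "vs" and to the left for genes lower in it. Of the comparisons drawn, CRES-1 vs RiPS1 (238 genes) and RiPS1 vs ORMES23 (267 genes) have the longest bars, and CRES-1 vs ORMES23 has none.

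ORMES23, derived from a fertilized embryo, served as the reference for each reprogrammed line. It is labelled male, so for the female lines CRES-3, RiPS2 and RiPS3 derivation and sex cannot be told apart. Against ORMES23, CRES-1 had 0 genes called by limma, with 1268 at an unadjusted p under 0.05. The genes with the smallest p, not called, were the heme exporter gene FLVCR1 at -1.20 (SE 0.19, n = 3 per line), FRMD3 at 1.10, LRRC63 at -1.65, ZNF573 at -1.02 and LRP11 at 1.96. HOX genes were higher as a group, with a median of 0.31 and HOXA5 at 0.80, though none of 19 was called over all genes or adjusted over the list alone (adjusted p = 9.92e-07, and 0.0406 with an estimated correlation). Members read only 3.79 to 6.99 in these lines, with 4 under log2 5 in both, so a shift near background stays open. Fibroblast genes had a median of 0.31 (adjusted p = 0.000239, and adjusted p = 0.248 with an estimated correlation) and cell cycle genes one of -0.29 (adjusted p = 0.0434, and adjusted p = 0.798 with an estimated correlation), which did not pass without ORMES23 A or CRES-1 C. The count was 3 without CRES-1 B, 12 without CRES-1 C and 40 without ORMES23 A, and 1 to 8 under the other settings that gave any call.

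CRES-3 differed from ORMES23 in 111 genes, 56 higher and 55 lower. The major histocompatibility gene MAMU-AG was 18.6-fold higher in CRES-3 (log2 4.21, SE 0.21, n = 3 per line), followed by the zinc finger genes ZNF799 (3.13, SE 0.45) and ZNF311 (3.07, SE 0.29), GCA (2.58), LOC712157 (2.41), the lipocalin LCN2 (2.33), the meiosis gene MEIOB (2.31) and the interferon-induced gene BST2 (1.29). MAMU-A read 2.23 higher on its brightest probe set and lower as the mean of its probe sets. LOC695105 fell by 3.11, with FOS at -3.02, the cell cycle inhibitor gene CDKN2A at -2.77, GATA3 at -2.70, ST6GAL2 at -2.52, TWIST1 at -2.22, CYP4X1 at -2.10 and TIPARP at -1.91. Genes that escape X inactivation had a median of 0.33 over 20 members, 0 called over all genes and 1 adjusted over the list alone (adjusted p = 0.000209, and adjusted p = 0.116 with an estimated correlation); PNPLA4 stood at 1.34, TXLNG at 0.92 and ZRSR2 at 0.72. Mesoderm genes had a median of -0.71 (-1.24 without ORMES23 A), 0 of 13 called and 3 adjusted over the list alone (adjusted p = 3.22e-05, and adjusted p = 0.115 with an estimated correlation), with EOMES at -2.26. TGF-beta and nodal genes had a median of -0.61 (-0.21 without ORMES23 A) and 1 of 20 fell, the activin antagonist FST (-1.27; 2 adjusted over the list alone; adjusted p = 0.000895, and adjusted p = 0.0520 with an estimated correlation). Fibroblast genes had a median of -0.23 (-0.10 without ORMES23 C and -0.15 without CRES-3 A) and fell in 2 of 37 cases, VIM (-1.28) and TWIST1 (5 adjusted over the list alone; adjusted p = 0.00159, and adjusted p = 0.348 with an estimated correlation). Neural genes had a median of -0.69, 0 of 7 called and 1 adjusted over the list alone (adjusted p = 0.0112, and adjusted p = 0.0713 with an estimated correlation). FOS lost its call without any single array of either line and GATA3 without most of them. The count was 194 without ORMES23 A, the array that stood apart from its line with high endoderm genes, and 54, 52, 63 and 61 without CRES-3 A, CRES-3 B, ORMES23 B and ORMES23 C.

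RiPS1 differed from ORMES23 in 267 genes, 201 higher and 66 lower. The transcription factor gene EBF2 was at least 4.04-fold higher in RiPS1 (log2 3.43, SE 0.48, n = 3 per line), followed by COL6A3 (3.05), HOXD1 (2.93), CRYGB (2.73), XG (2.57), G0S2 (2.57), the X-linked matrix gene MXRA5 (2.53) and LOC708877 (2.51). FAIM fell by 4.04 (SE 0.32), with PEG3 at -3.65 (SE 0.31), DHRS2 at -3.01, SCD5 at -2.59, UBD at -2.54, GATA3 at -2.32, the metallothionein gene MT1E at -2.30 and LOC695105 at -2.06. Of 46 X-linked genes called, 43 rose. Escape genes had a median of 0.71; 4 of 20 rose, over all genes and adjusted over the list alone (adjusted p = 1.15e-10, and 0.0316 with an estimated correlation), including TXLNG (1.22), CA5B (1.17) and CTPS2 (1.07). Genes subject to inactivation rose in 5 of 93 cases, 6 adjusted over the list alone (adjusted p = 0.000466, and adjusted p = 0.156 with an estimated correlation), including CFP (1.80), PLP2 (1.11) and FGD1 (1.09). Epithelial genes were lower as a group, with a median of -0.49, 0 of 21 called and 1 adjusted over the list alone (adjusted p = 1.26e-05, and 0.0316 with an estimated correlation); CLDN7 stood at -0.98 and DSP at -0.92. Neural and mesoderm genes had medians of -0.63 and -0.76 with none called (adjusted p = 0.0219 and 0.0408; with an estimated correlation, adjusted p = 0.103 and 0.457), and neither list passed without RiPS1 B, where the neural median was -0.39; the mesoderm list also failed to pass without RiPS1 A or ORMES23 B. Without ORMES23 A, 362 genes were called, 233 higher and 129 lower.

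RiPS2 differed from ORMES23 in 51 genes, 21 higher and 30 lower. LOC712157 was 13.1-fold higher in RiPS2 (log2 3.71, SE 0.37, n = 3 per line), MAMU-AG 9.55-fold (3.26, SE 0.21), ZNF799 by 2.54, ZNF311 by 2.27, SP140 by 1.82, GCA by 1.81, HSBP1L1 by 1.79 and SH3YL1 by 1.69. LOC695105 fell by 3.62 (SE 0.28), with UBD at -3.06, the paternally expressed imprinted gene MEST at -2.64, SECISBP2L at -2.21, ATP8A2 at -1.71, RARRES1 at -1.65, the histocompatibility gene MAMU-B at -1.62, C19H19orf12 at -1.55 and the interferon-induced gene MX1 at -1.36; ATP8A2 and RARRES1 lay under log2 5 in both lines. Escape genes had a median of 0.45, with TXLNG called at 1.05 and ZRSR2 at 0.74, not called; 1 of 20 rose, and 2 adjusted over the list alone (adjusted p = 5.15e-09, and 0.0316 with an estimated correlation). HOX genes had a median of 0.39, and 1 of 19 rose, HOXD13 (1.32), also adjusted over the list alone (adjusted p = 1.26e-05, and adjusted p = 0.0591 with an estimated correlation); its members read only 3.79 to 6.94 in these lines. Epithelial genes had a median of 0.18 (0.08 without RiPS2 A), 0 of 21 called and 1 adjusted over the list alone (adjusted p = 0.00986, and adjusted p = 0.115 with an estimated correlation). Endoderm genes had a median of -1.44 with 0 of 11 called and 1 adjusted over the list alone (adjusted p = 0.0176, and adjusted p = 0.471 with an estimated correlation); ORMES23 A, the array with high endoderm genes, carries much of it, as the median was -0.65 without that array and did not pass, nor did it without RiPS2 B. The count was 27 without RiPS2 A, 32 without ORMES23 B and 30 without ORMES23 C, and without RiPS2 B 48 genes were lower. A fit of these arrays alone called 11 genes.

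RiPS3 differed from ORMES23 in 86 genes, 52 higher and 34 lower. MAMU-AG was 19.7-fold higher in RiPS3 (log2 4.30, SE 0.21, n = 3 per line), followed by TESMIN (3.26, SE 0.52), ZNF311 (2.89), the glutathione transferase gene GSTK1 (2.57), LOC712157 (2.53), XG (2.19) and TTLL6 (2.16). MAMU-A read 2.61 higher on its brightest probe set and lower as the mean of its probe sets. LOC695105 fell by 2.51, with ST6GAL2 at -2.48, PTPRB at -2.30, the mesenchymal factor gene ZEB1 at -2.14, MEST at -2.10, LOC707924 at -1.70, FAM111A at -1.66 and CENPO at -1.59. Epithelial genes had a median of 0.31 (0.18 without ORMES23 C); 2 of 21 rose, RAB25 (1.68) and CLDN7 (1.37), also adjusted over the list alone (adjusted p = 0.000597, and adjusted p = 0.0526 with an estimated correlation). Escape genes had a median of 0.30 and 1 of 20 rose, PNPLA4 (2.01), also adjusted over the list alone (adjusted p = 0.000146, and adjusted p = 0.115 with an estimated correlation). Paternally expressed imprinted genes had a median of -0.09, with MEST the only call of 11, also adjusted over the list alone (adjusted p = 0.0286, and adjusted p = 0.140 with an estimated correlation). Neural genes had a median of -0.56 with 0 of 7 called (adjusted p = 0.0371, and adjusted p = 0.116 with an estimated correlation); its median was -0.88 without ORMES23 A, and it did not pass without RiPS3 A, RiPS3 C or ORMES23 C. The imprinted list did not pass without RiPS3 A or ORMES23 A, and its median lay between -0.27 (without RiPS3 B) and -0.07 (without RiPS3 A). The count was 182 without RiPS3 A, 34 without RiPS3 B, 44 without RiPS3 C and 49 without ORMES23 C; without ORMES23 A 64 genes were lower, and without ORMES23 B 18. A fit of these arrays alone called 27 genes.

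CRES-3 and RiPS3 shared 43 calls against ORMES23, 26 higher and 17 lower, where independent lists would share 0.26 and 0.17. Their differences correlated at r = 0.738 across genes with a covariance of 0.0917, against 0.504 and 0.0276 for simulated unchanged groups. Part of this excess may come from the shared ORMES23 arrays. CRES-3 and RiPS3 are both labelled female and ORMES23 male, so a difference of sex cannot be told apart in the shared calls. A shared donor of CRES-3 and RiPS3, which the design text leaves possible, was not tested.

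X-linked genes were compared between the labelled sexes of the pluripotent lines. RiPS1, a male line, stood apart: its X-linked genes lay 0.28 ± 0.11 (SD, n = 3) above its autosomal genes on the log2 scale. The other male lines stood at 0.03 (ORMES23) and 0.02 (CRES-1), and the female lines at -0.01 (CRES-3), 0.01 (RiPS2) and 0.06 (RiPS3). Female minus male lines gave -0.09 (exact permutation p = 0.4, two-sided, 3 lines per sex; 0.1 is the smallest p this design can give). Gene by gene, the median of 423 X-linked genes lay -0.08 from that of autosomal genes (camera p = 0.00127, adjusted p = 0.00329, and adjusted p = 0.473 with an estimated correlation). Without RiPS1 it was -0.02 and did not pass.

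**Figure D2:**
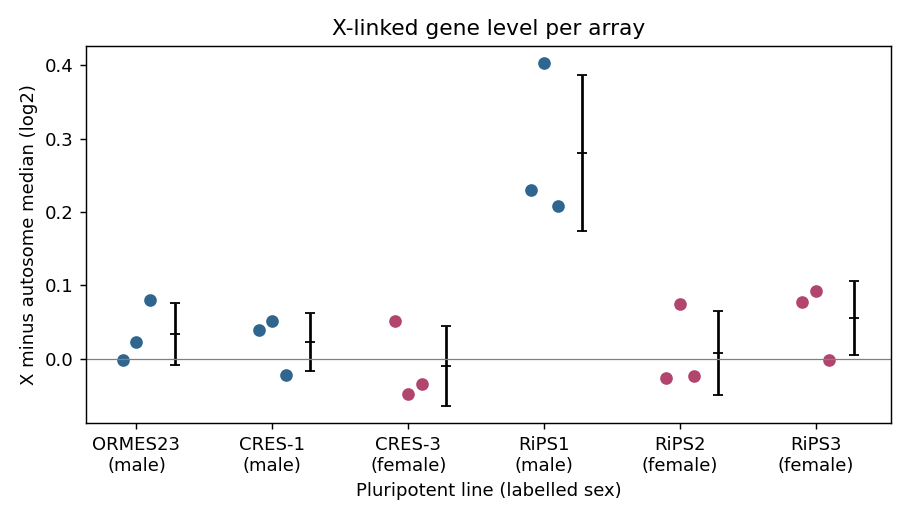
Median log2 value of X-linked genes minus that of autosomal genes (vertical axis) for each array of the 6 pluripotent lines; points are arrays, coloured by labelled sex (blue male, red female), and bars are the mean and SD of the 3 arrays. The 3 RiPS1 arrays lie at 0.21 to 0.40, above every other array.

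Line pairs of 1 route gave the same picture. RiPS2 and RiPS3 lay below RiPS1 over X-linked genes by -0.20 and -0.14 (adjusted p = 1.74e-06 and 1.84e-07; with an estimated correlation, adjusted p = 0.00507 for both), with 48 of 402 and 45 of 272 called genes being X-linked and lower. CRES-3 against CRES-1 gave -0.02 (adjusted p = 0.785, with 291 genes called in all), while escape genes alone were 0.33 above autosomal genes, with 16 of 20 above 0 (adjusted p = 0.00512, and adjusted p = 0.168 with an estimated correlation). Escape genes went the other way against RiPS1, with 5 of 20 above 0 in each pair. They stood at -0.24 in RiPS2 and -0.35 in RiPS3 (camera adjusted p = 0.0301 and 0.000165, and adjusted p = 0.312 and 0.0684 with an estimated correlation). Across line means, 2 genes differed between the sexes. SH3YL1 was 3.42-fold higher in female lines (1.78, SE 0.13, 3 lines per sex) and the hematopoietic factor gene LMO2 was lower (-1.21, SE 0.08); 860 genes had an unadjusted p under 0.05, and without any 1 of the 6 lines the count was 0. With derivation as a block it was also 0, and with line as a random block over all arrays 21. The SRY probe set read 5.48 ± 0.15 (SD, n = 3) in ORMES23 and 6.08 ± 0.29 in CRES-3 and did not follow the labelled sex.

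**Figure D3:**
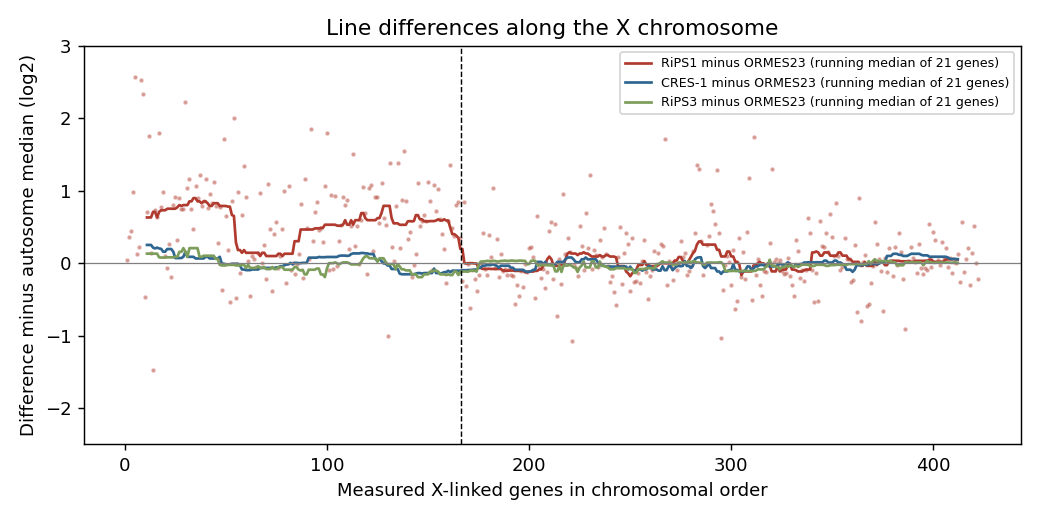
Log2 difference of each line from ORMES23, minus the autosomal median (vertical axis), for 422 X-linked genes in chromosomal order (horizontal axis); points are RiPS1 genes, lines are running medians for RiPS1, CRES-1 and RiPS3, and the dashed line marks the largest split. RiPS1 has a median of 0.59 over the 166 genes left of the split, with a dip inside that stretch, and 0.00 right of it.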

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

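The test of a difference between the route effects of female and male lines was chosen after the counts of both comparisons were seen, as was the search for probe sets that separate the labelled sexes. CRES-3 minus RiPS3 and CRES-1 minus RiPS1 differed in 322 genes by a test of the difference itself, and each value here is the female effect minus the male effect on the log2 scale. In this direction FOS stood at -5.53, FAIM at -4.00, RGS4 at -3.78, DHRS2 at -3.23, SEMA3C at -3.13, S100A6 at -3.08, BMP4 at -2.60, ATP8A2 at -2.38, PEG3 at -2.38, TBXT at -2.16, JUNB at -2.0, KLF4 at -1.97, HOXA5 at -1.50 and ZNF662 at -1.38. EBF2 stood at 3.82, LRRC63 at 3.59, the collagen gene COL6A3 at 3.31, HOXD1 at 2.78, XG at 1.85, SVOPL at 1.81, CHST8 at 1.67 and LOC708877 at 1.56. X-linked genes among them were CFP (1.58), EIF2S3 (1.45), CTPS2 (1.40), FGD1 (1.26), CA5B (1.26), PHKA2 (1.21) and PRPS2 (1.14). Each was higher in RiPS1 than in CRES-1, but RiPS1 is not the only line that contributes. CRES-3 lay above CRES-1 by 0.72 for EIF2S3, 0.63 for CTPS2 and 0.40 for CA5B. The count of 322 was 194 without CRES-3 A, 208 without CRES-3 B, 186 without CRES-1 A, 202 without RiPS1 A and 199 without RiPS1 B. Lines and sexes differ together here, and donors may too, so the difference is one between 4 lines.

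Probe sets without a gene name, outside the genes compared, separated the labelled sexes of the pluripotent lines. MmugDNA.20222.1.S1_s_at read 11.6, 11.3 and 11.5 in CRES-3, RiPS2 and RiPS3 and 3.76, 3.75 and 4.05 in ORMES23, CRES-1 and RiPS1, a gap of 7.13. The female fibroblasts lay between, at 8.86. MmugDNA.39107.1.S1_at had a gap of 6.01 in the same direction. MmugDNA.13186.1.S1_at was high in the male lines (10.1, 10.7 and 9.89) and low in the female lines and the fibroblasts (3.22), with a gap of 6.01. In all, 7 probe sets were higher by at least 2 in every female line and 7 in every male line. All 7 of the first kind and 6 of the second carry no gene name; the other is 1 of several probe sets named RERE, whose brightest one did not separate the sexes. These probe sets were picked for that gap, so they are no test of the labels.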

How the results depend on the processing

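The tests without X-linked genes, the list tests with an array left out and every setting of the difference between female and male route effects were chosen after results were seen. Dropping the fold limit raised the counts to 7205 for CRES-3 and 7020 for RiPS3 against the fibroblasts, 8 for CRES-3 against RiPS3 and 797 for CRES-1 against RiPS1, by construction. Against ORMES23 it gave 280 for CRES-3, 929 for RiPS1, 105 for RiPS2 and 218 for RiPS3, and 543 for the difference between route effects. Fits of only the arrays compared gave 7 genes for CRES-3 against RiPS3, 1 for CRES-1, 11 for RiPS2 and 27 for RiPS3 against ORMES23; the cause was not tested. CRES-1 against ORMES23 had 1 gene with the log2 filter of 7, 1 with median centring, 1 with the mean of all probe sets and 8 with a replicate block. That block, fitted in each comparison of arrays, moved no other count by over 1.5 times. All letters moved together only for CRES-1 and RiPS1. Female against male lines had 1 gene with the filter of 7, 4 with the mean of probe sets, 21 with line as a random block and 0 with derivation as a block or with any line left out. With 1 array left out the counts ran from 1 to 20 for CRES-3 against RiPS3, 0 to 40 for CRES-1 against ORMES23, 52 to 194 for CRES-3, 27 to 74 for RiPS2 and 34 to 182 for RiPS3 against ORMES23, and 186 to 435 for the difference between route effects. For X-linked genes, female against male lines, the median ran from -0.11 without CRES-1 to -0.023 without RiPS1; it was -0.068 for genes subject to inactivation and 0.10 for escape genes. CRES-3 against CRES-1 gave 0.034 and 0.33 for these lists. Without the filter on dim probe sets the X-linked median was -0.045 for female against male lines. It was then -0.091 for RiPS2 and -0.068 for RiPS3 against RiPS1, smaller than with the filter. Of 42 list calls 10 passed with an estimated correlation, while fry called 71, and with 1 array left out 37 to 48 passed. The mean of all probe sets reversed FBN1, CRES-3 vs fibroblasts, to -3.79, and FBN1, RiPS3 vs fibroblasts, to -3.22. It also reversed MAMU-A, CRES-3 vs ORMES23, to -1.29, and MAMU-A, RiPS3 vs ORMES23, to -1.05; probe sets of these genes disagree. Over 3857 alternatives of 282 named gene results, 3613 gave the same call, 210 a weaker one, 30 a stronger one and 4 a reversed one. The filter of 7 moved the median of all genes by 0.15 and 0.12 in CRES-3 and RiPS3 against the fibroblasts, and median centring moved it by -0.12 in CRES-3 against the fibroblasts and by 0.12 in CRES-1 against RiPS1.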

Other observations

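The gene groups and line profiles of this part were described after results were seen, and the tests of the RiPS1 X chromosome, of X-linked genes and single arrays in the route counts, of ORMES23 A, of neighbouring genes and of splits for the 322 genes were chosen then too; the route test and the other counts of splits were chosen before their values were seen. No list in this paragraph or the next passed against the fibroblasts, so the values, given for CRES-3 and then RiPS3, stand for single genes. Of 18 polycomb and DNA methylation genes, 8 rose and 2 fell in CRES-3 (adjusted p = 0.0661) and 9 and 2 in RiPS3 (adjusted p = 0.0514): the demethylating enzyme gene TET1 rose by 6.49 (SE 0.30, n = 3 per line) and 5.73, DNMT3A by 4.47 and 4.25 and JARID2 by 3.60 and 3.53. Of 12 cell cycle inhibitor genes, 4 fell and 1 rose in CRES-3 (adjusted p = 0.210) and 4 fell in RiPS3 (adjusted p = 0.214); CDKN1A (p21) stood at -4.84 and -4.65, CDKN2A at -3.95 and -2.88 and CDKN2C at -3.44 and -3.32. Of 16 glycolysis genes, 5 rose and 2 fell in CRES-3 (adjusted p = 0.210) and 4 and 3 in RiPS3 (adjusted p = 0.477), the glucose transporter genes SLC2A1 (3.50 and 3.04) and SLC2A3 (2.89 and 2.92), ALDOC (2.84 and 2.66) and PDK1 (2.21 and 2.28) among those that rose. Of 21 respiratory genes only SDHA was called, at -1.56 and -1.48. Imprinted genes went both ways: MEST rose by 5.74 and 4.22, PEG3 by 3.28 and 2.86 and SNRPN by 2.22 and 2.02, while SGCE stood at -3.35 and -3.66, DIRAS3 at -4.89 and -4.86, TFPI2 at -4.61 and -4.34 and ATP10A at -2.74 and -2.72.

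Of 17 histocompatibility and interferon genes, 5 rose and 5 fell in CRES-3 (adjusted p = 0.365) and 4 and 5 in RiPS3 (adjusted p = 0.330); TAPBP stood at -3.37 and -3.43, PSMB8 at -2.74 and -2.63, IFITM1 at 3.79 and 3.61 and MX1 at 2.49 and 2.74. Of 20 TGF-beta and nodal genes, 5 rose and 5 fell in CRES-3 and 6 and 5 in RiPS3, with INHBA at -4.19 and -3.45, TGFB3 at -2.65 and -2.60, BMP4 at 3.54 and 4.62 and BMP7 at 2.40 and 2.56. Single lineage genes rose: the neural factor gene SOX3 by 3.69 and 4.04 (2 of 7 neural genes rose and 1 fell in each line) and the mesoderm factor gene EOMES by 2.72 and 3.81 (2 of 13 rose and 3 fell in CRES-3, 4 and 2 in RiPS3). Of 11 endoderm genes, 5 rose and 1 fell in CRES-3 and 6 and 1 in RiPS3, with CER1 at 3.11 and 4.57 and the keratin gene KRT7 at -4.33 and -4.51, and of 3 germline genes SOHLH2 rose, by 3.55 and 3.18. DUSP1 stood at -3.50 and -2.91 and EGR2 rose by 2.59 and 3.38. X-linked genes moved in both directions, with AP1S2 at 4.87 and 4.76, TSPAN7 at 4.59 and 4.59, TXLNG at 2.09 and 1.86 and MAOA at -4.86 and -4.54; CHIC1 rose by 1.89 and 1.67 on its brightest probe set. Of 23 lists, 9 passed in no comparison, the cell cycle inhibitor and the polycomb and methylation lists among them.

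For the X-linked rise in RiPS1, a single array is argued against, since the lowest RiPS1 array still had X-linked genes 0.21 above autosomal ones, and cells of a female line are argued against, since over all X-linked genes the highest female line (RiPS3) stood at 0.056 and a mixture lies between its sources. A gain of part of the X chromosome may explain it: the 166 genes at one end of the order (GTPBP6 to SPIN3 in the telomere-to-telomere assembly MMU8v2.0) had a median of 0.59, with a dip inside the stretch, and the other 256 one of 0.00, with a permutation p of 1e-04, the smallest the shuffles can give. A low split p alone is not particular to RiPS1, since pairs without it, such as ORMES23 and RiPS2 (permutation p = 0.001, the smallest for these pairs) or CRES-3 and RiPS3 (0.003), also beat shuffled order, with smaller differences at other places (-0.33 after 44 genes and -0.24 after 20, against 0.54 after 166). Against CRES-1, CRES-3, RiPS2 and RiPS3 the first part of RiPS1 stood at 0.56, 0.62, 0.54 and 0.59. It holds 35 of the 43 X-linked genes called higher against ORMES23. The split was placed on that same comparison, so this share follows from its place and adds no support. All 17 ordered escape genes lie in the first part, so the escape list in RiPS1 cannot speak for X inactivation. No DNA was used here, and a regulated change over this stretch stays open and untested.

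The second pattern is the larger count for CRES-1 against RiPS1 (238) than for CRES-3 against RiPS3 (4). Over the 238 genes, a route effect common to both sexes was not seen. CRES-3 minus RiPS3, turned to the same direction, had a median of -0.077, with 84 genes of the same sign and 154 of the opposite one. As CRES-3 and RiPS3 were the closest pair (mean absolute difference 0.17), this test partly restates the pattern and cannot decide on the route. CRES-3 against CRES-1, both cloned, called 291 genes, so a count of this size also arises within a route. The X-linked genes of RiPS1 do not account for it, as 262 genes outside X differed between the comparisons, nor does a single array, as the lowest count with 1 array left out was 176 against a highest of 20. Over the 238 genes ORMES23 (1.07 from RiPS1), RiPS2 (1.10) and RiPS3 (0.74) lay nearer CRES-1 than RiPS1, and CRES-3 (0.63) lay midway. A state of the RiPS1 line is therefore a candidate explanation. The closeness of CRES-3 and RiPS3 is another part of the pattern, and its cause was not tested. The fetal fibroblast origin of RiPS1 and its donor stay open and were not tested.

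The third pattern is ORMES23 A, whose removal raised several counts. Cells expressing endoderm genes are a candidate explanation: the endoderm list stood 1.60 above ORMES23 B and C, at percentile 100 of 10000 random lists, with CER1 at 11.7 against 7.59 and 7.19, GATA6 at 11.2 against 8.17 and 6.90, CXCR4 at 11.2 against 7.91 and 7.79, SOX17 at 10.5 against 8.02 and 7.22 and FOXA2 at 9.53 against 6.63 and 6.25. AFP (7.65 against 7.85 and 7.94) and KRT7 (5.80 against 6.64 and 6.92) did not follow. APOA1 lay between B and C (8.74 against 8.99 and 8.25), and HHEX moved little (12.4 against 12.1 and 12.3). The endoderm list was not alone at the extremes. Glycolysis genes (0.49, percentile 100) and cell cycle genes (0.19, percentile 99.4) were higher. Mesoderm, trophoblast and neural genes were lower (-0.52, -0.51 and -0.58, at percentiles 0, 0.01 and 0.11). The reprogramming factors were lower too (-0.53, percentile 0.18 of the random lists). ORMES23 B and C also read at least 7 in 7 of 11 endoderm members, so partial differentiation in that culture and a change of state of all its cells stay open. RNA degradation stays open too: the actin 3 prime to 5 prime difference was 1.64 in ORMES23 A against 0.85 and 0.79 in B and C, while that of GAPDH (0.71 against 0.63 and 0.76) did not follow, and CRES-3 C, with the largest actin difference (2.17), still correlated with its line at 0.992, against 0.969 for ORMES23 A.

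Other splits of the same 6 arrays were counted for each pair of lines. With 10 splits the share cannot fall under 0.05; 1 split, the real one, gave as many genes in each comparison except CRES-1 against ORMES23. Real and highest other counts were 3709 and 0 for CRES-3 and 3621 and 0 for RiPS3 against the fibroblasts, 4 and 0 for CRES-3 against RiPS3, and 238 and 2 for CRES-1 against RiPS1. Against ORMES23 they were 111 and 0 for CRES-3, 267 and 106 for RiPS1, 51 and 9 for RiPS2 and 86 and 29 for RiPS3, and 2 and 0 for female against male lines. For CRES-1 against ORMES23 the real count was 0, which each of the 10 splits reaches, so the number that reach it says nothing; the split of ORMES23 A, CRES-1 A and CRES-1 B from ORMES23 B, ORMES23 C and CRES-1 C gave 57. It follows the first component of the spread within lines (32.6% of that variance, with scores of 29.8, 5.85 and 8.84 against -14.0, -15.9 and -14.7), so a structure of the samples other than the line is present. Endoderm genes weigh in it, with the median loading of that list at percentile 97.9. It is not limited to ORMES23 A, as RiPS2 B (15.8) and RiPS1 B (11.5) also scored above 0. The letters of CRES-1 and RiPS1 moved together, though a pairing of their samples is not established. Of the 4 splits of that comparison that part every letter, the real one gave 238 and the others at most 0. For the 322 genes of the route difference, 1 of 100 splits, the real one, gave as many, with 176 the highest other, a count chosen after the 322 were seen. Most of these splits mix CRES-1 with RiPS1, which removes the difference between those lines and leaves at most 4 genes, so they do not speak to the route difference. Of the 20 splits that keep CRES-1 and RiPS1 apart, 1, the real one, gave as many, with 185 the highest other; a share under 0.05 is out of reach with these.

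Neighbouring genes moved together in 9 windows of 41 genes over the 6 lines, each line set against the median of the other 5. RiPS1 had a median of 0.54 over RPS6KC1 to MIXL1 on chromosome 1, with 35 of 41 genes above 0, and 0.77 over KCND1 to MAGEH1 on X, with 38 above 0 (permutation p = 0.00498 for both, the smallest the 200 shuffles can give). RiPS3 stood at -0.35 over CCDC74B to TMEM163 on chromosome 12 (37 of 41 below 0). ORMES23 stood at -0.22 over LOC719811 to PHKA2 on X (34 of 41 below 0), a window with 12 escape genes. Against ORMES23 the escape list stood 0.31, 0.44 and 0.29 above autosomal genes in CRES-3, RiPS2 and RiPS3 (adjusted p = 7.23e-05, 1.45e-09 and 5.86e-05; with an estimated correlation, adjusted p = 0.0619, 0.00514 and 0.0619). In the male line CRES-1 it stood at 0.08 (adjusted p = 0.552), though 15 of 20 members lay above 0, and in the male line RiPS1 at 0.70. Between CRES-3 and CRES-1, which do not involve ORMES23, it stood at 0.33 (adjusted p = 0.00512, and adjusted p = 0.168 with an estimated correlation). These values have the direction of escape from X inactivation in female lines, but over all 6 lines, RiPS1 included, female minus male gave 0.10 and did not pass (adjusted p = 0.372).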
